A study of Homo sapiens with 24 samples.

How the data were processed

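Messenger RNA was sequenced from 4 human leukaemia cell lines, each with vehicle or 100 nM GEX1A for 6 h, 3 libraries per group and 24 libraries in 8 groups. The authors' deposited table gives whole-number raw counts per gene, checked to sum to between 14410963 and 27548121 per library. The deposited FPKM values equal the counts scaled by gene length and by the library's total count, and both deposited copies match within a relative difference of 0.000676. The deposited signal columns are counts divided by 1 size factor per library, set within each line by the authors. The authors' log2 fold changes, p-values and adjusted p-values compare treated with vehicle within each line, per the file headers. The submitters' notes name DESeq2 and hg38 without versions, and the aligner, the counting tool and the strand of counting are not given in the sources used here. The 8 group mean columns were not used, and 0 per-sample columns matched no sample.

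Groups were taken from the sample labels. Genes with FPKM of at least 1 in at least 3 libraries were tested, 16091 of 58676. Counts were fitted with the quasi-likelihood model of edgeR 4.0.16 in R 4.3.3, with TMM scaling and 1 mean per group (16 residual degrees of freedom, common dispersion 0.00683). Tests were two-sided, adjusted by Benjamini-Hochberg within each contrast, and called at adjusted p under 0.05. The comparisons were the GEX1A effect in each line, the difference between the mean effects of the sensitive and the resistant lines, the vehicle libraries of the classes, and the genes called in the same direction in all 4 lines. A class difference was counted only where the contrast passed and each of the 4 pairs of a sensitive and a resistant line had the same sign at unadjusted p under 0.05. The comparisons, gene lists, rule for named genes and alternatives were fixed before the data were examined. The design had assumed FPKM alone and limma on log2(FPKM + 1). As counts were found in the table, edgeR took its place after seeing the data, and the planned limma test (limma 3.58.1) became an alternative. Library totals, RLE factors and DESeq2 1.42.0 were added after seeing the data.

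Named genes are, per line, the 5 protein-coding genes with the largest rise and the 5 with the largest fall in log2(FPKM + 1) among those called, with mean FPKM of at least 5 in the higher group and all 3 treated libraries beyond all 3 vehicle libraries. To these were added the 8 largest in each direction of the class contrasts and of the changes shared by all lines, up to 4 members of each list, and a fixed set (SF3B1, PHF5A, SF3B3, MCL1, BCL2L1, BCL2, TP53, CDKN1A, MDM2, MYC, FLT3, HOXA9, MEIS1, GATA1 and MPO). Genes of chromosome Y were left out of the naming in class contrasts. The 33 fixed lists and the list of protein-coding genes with 1 exon were tested with camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, which asks whether the genes move one way on balance. Of the 34 lists, camera called 16 in Molm-13, 20 in MV4:11, 17 in HL-60, 13 in K562, 10 for the response difference and 13 for the vehicle comparison. With an estimated correlation 2, 2, 1, 1, 3 and 2 were called, and by fry 28, 27, 29, 29, 21 and 29. Counts adjusted over the list alone are given where they differ from those over all genes tested. Lists share members: 7 of the 25 p53 targets, 12 of the 25 immediate early genes and 58 of the 250 single-exon genes are also in another list.

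A fitted change against a group with no count depends on the prior count. List and exon-class medians were therefore also taken at the bound, with such a group set to 3 counts over its 3 libraries and genes with at most 3 counts in every group of the contrast left out. The bound covers counting error only, and was added after seeing the results. Exon numbers and overlaps came from GENCODE v29, which holds all 58676 gene identifiers (95.3% with the same start and end), for 19473 of 19821 protein-coding genes. Alternatives were other scalings (upper quartile, quantile normalization, the TPM scale), pseudocounts of 0.1 and 0.5, other filters, protein-coding genes only, a robust fit, a fit of each comparison's own libraries, a replicate block and leaving out each library. Simulations changed 200 of 16091 genes and do not give the error where most genes change. In Molm-13 edgeR recovered 24, 60, 82 and 88% of 1.25, 1.5, 2 and 4-fold changes (3.05% of calls false). Limma recovered 10, 56, 80 and 88% (24.5% false) and the class rule 16, 58, 82 and 88% (1.61% false). That 1.61% does not cover lines that respond differently: other groupings of the real lines gave 894 and 1303 genes, against 1182. For camera, a simulated raised list of 98 genes had adjusted p = 4.01e-172, and 0 of 33 random lists were called. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 prepared tables and figures.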

Results

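GEX1A, a splice modulator per the series title, was given at 100 nM for 6 h to 4 human leukaemia cell lines, and plain medium served as the vehicle. Molm-13 and MV4:11 are acute myeloid leukaemia lines with MLL fusions that the labels class as sensitive. HL-60, a promyelocytic line, and K562, a chronic myeloid leukaemia line, are classed as resistant. Each of the 8 groups had 3 libraries, 24 in all. The sensitive lines were grown in RPMI medium and the resistant lines in DMEM, and the labels list TP53 among the mutations of both resistant lines, so class, medium and listed TP53 status go together. Values given for the 4 lines follow the order Molm-13, MV4:11, HL-60 and K562. The labels do not say whether replicates were separate cultures, so p-values measure the spread between these libraries.

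Mitochondrial transcripts took 5.32 ± 0.342% of counts in Molm-13 vehicle and 8.35 ± 0.546% with GEX1A (mean ± SD, n = 3). The share went from 4.12 ± 0.439% to 5.57 ± 0.233% in MV4:11 and from 6.69 ± 0.0460% to 11.7 ± 0.787% in HL-60, while in K562 it was 5.79 ± 1.08% with vehicle and 3.99 ± 1.26% with GEX1A. The 10 most abundant genes of each library held 8.37% of counts with vehicle and 11.3% with GEX1A in Molm-13, 6.85% and 8.87% in MV4:11, 8.63% and 13.7% in HL-60, and 7.29% and 6.82% in K562. K562 GEX1A replicate 2 stood apart from its replicates, with 5.40% mitochondrial counts against 3.58% and 2.98%, and K562 vehicle replicate 3 with 7.03% against 5.24% and 5.09%. Gene levels are given as mean FPKM ± SD over 3 libraries, with vehicle first. FPKM is not scaled for composition, so a fitted change can differ in sign from the FPKM means: MDM2 in HL-60 stood at 2.26 ± 0.0757 with vehicle and 2.18 ± 0.20 with GEX1A with a fitted log2 change of 0.43.

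The effect of GEX1A was first compared across the lines, to see which transcripts changed in all of them. EIF4A1, the RNA helicase of translation initiation, rose from 4.76 ± 1.99 to 38.6 ± 5.92 in Molm-13, from 1.60 ± 0.302 to 41.1 ± 2.88 in MV4:11, from 5.05 ± 0.472 to 71.6 ± 3.11 in HL-60 and from 0.901 ± 0.401 to 9.92 ± 0.372 in K562 (FPKM, mean ± SD, n = 3). DEXI rose from 2.24 ± 0.468 to 16.0 ± 1.16, from 2.51 ± 0.216 to 21.5 ± 1.79, from 1.53 ± 0.431 to 23.1 ± 1.09 and from 3.41 ± 0.469 to 41.4 ± 0.695 in the same order of lines. The zinc finger gene ZNF324 rose from 3.05 ± 0.424 to 17.1 ± 0.18 in Molm-13, and ZNF394 from 7.41 ± 0.345 to 24.8 ± 1.75. TSSC4, which codes for a U5 snRNP-associated protein, rose from 19.8 ± 1.3 to 71.3 ± 5.99 in K562, LRRC14 from 6.21 ± 0.162 to 26.0 ± 1.67, the ribosomal protein gene RPS10 from 1.56 ± 0.512 to 8.84 ± 1.80, and EMC6, a subunit of the ER membrane complex, from 0.652 ± 0.293 to 6.17 ± 4.86. Among the largest shared falls, the Mediator subunit MED18 fell from 14 ± 1.27 to 2.04 ± 0.467 in Molm-13, from 21.8 ± 0.380 to 2.75 ± 0.202 in MV4:11, from 12 ± 0.302 to 1.31 ± 0.675 in HL-60 and from 16.7 ± 0.615 to 2.45 ± 0.353 in K562. CHAF1A, the large subunit of chromatin assembly factor 1, fell from 29.3 ± 0.498 to 5.24 ± 0.625, from 34.1 ± 0.743 to 3.67 ± 0.425, from 19.5 ± 0.569 to 2.51 ± 0.372 and from 24.4 ± 0.794 to 4.82 ± 0.670. In MV4:11 the calcium channel gene ORAI1 fell from 20.9 ± 2.01 to 3.04 ± 0.473, JAGN1 of the endoplasmic reticulum from 25.6 ± 2.63 to 3.28 ± 0.733, FAM117A from 20.7 ± 1.01 to 0.467 ± 0.217, ZFYVE27 from 9.47 ± 0.593 to 1.36 ± 0.159, the ER mannosidase gene EDEM3 from 15.4 ± 0.813 to 2.21 ± 0.211 and the transcription factor gene NFIC from 13 ± 0.753 to 2.53 ± 0.375, and each also fell in the other 3 lines.

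By edgeR, 2472 genes rose and 2710 fell in all 4 lines, 5182 of the 16091 tested. Across the 9399 genes expressed in all 4 lines, the log2 changes of Molm-13 correlated with those of MV4:11 at Pearson 0.887 and Spearman 0.879, and those of HL-60 with K562 at 0.768 and 0.693, the lowest Pearson of the 6 pairs. These are correlations across genes, which are not independent replicates. The split between rises and falls depends on the scaling, since the median change of all genes shifted from its TMM value by -0.32, -0.31, -0.47 and -0.23 by library totals, and by -0.49, -0.46, -0.74 and -0.21 with FPKM rescaled to a common sum (the TPM scale, or by TPM). It shifted by 0.10, 0.07, 0.17 and 0.04 by upper quartiles and 0.11, 0.09, 0.15 and -0.01 with RLE factors. The shared counts (up and down) were 1470 and 4029 by library totals, 1082 and 4339 on the TPM scale, 2777 and 2376 by upper quartiles, 2691 and 2481 with RLE factors and 2678 and 2509 by DESeq2. On the same strand, another gene overlaps 48.6% of the exonic bases of EIF4A1, 39.4% of RPS10 and 25.1% of ZNF324. On either strand it overlaps 36.1% of DEXI, 74.2% of EMC6 and 27.7% of LRRC14. How shared reads were counted is not given, so these levels and changes are uncertain.

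Because GEX1A is named as a splice modulator, changes were set against the number of annotated exons. Genes with 1 exon had median log2 changes of 1.12, 1.58, 1.14 and 1.19 in Molm-13, MV4:11, HL-60 and K562 (SD over treated libraries 0.0964, 0.0240, 0.0895 and 0.168), over 1446, 1390, 1647 and 1536 expressed genes. Genes with over 10 exons had medians of -0.36, -0.33, -0.41 and -0.23 (SD 0.00102, 0.0206, 0.0195 and 0.0342), over 4348, 4276, 4573 and 4542 genes. Among protein-coding genes alone, the single-exon medians were 0.98, 1.15, 0.92 and 0.87 and those over 10 exons -0.36, -0.34, -0.41 and -0.24. With genes that had no count in one group placed at a bound of 3 counts over that group, the single-exon medians of all tested genes were 1.11, 1.46, 1.13 and 1.19. Called up and down were 53.3 to 62.3% and 8.42 to 12.4% of expressed genes with 1 exon, and 25.7 to 28.7% and 50.3 to 57.4% of those with over 10. As a tested list of 250 genes, single-exon protein-coding genes moved as follows: 146 rose and 21 fell in Molm-13, 154 rose and 14 fell in MV4:11, 137 rose and 27 fell in HL-60 and 137 rose and 30 fell in K562, with median log2 changes of 0.85 (0.88 at the bound), 0.98 (1.02 at the bound), 0.71 (0.76 at the bound) and 0.75 (0.78 at the bound), 0.00 on the TPM scale in HL-60. This list had adjusted p = 1.75e-10, 2.58e-11, 1.11e-07 and 2.31e-08 by camera. This became adjusted p = 0.0754, 0.0579, 0.127 and 0.126 with an estimated correlation in all 4 lines.

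**Figure D1:**
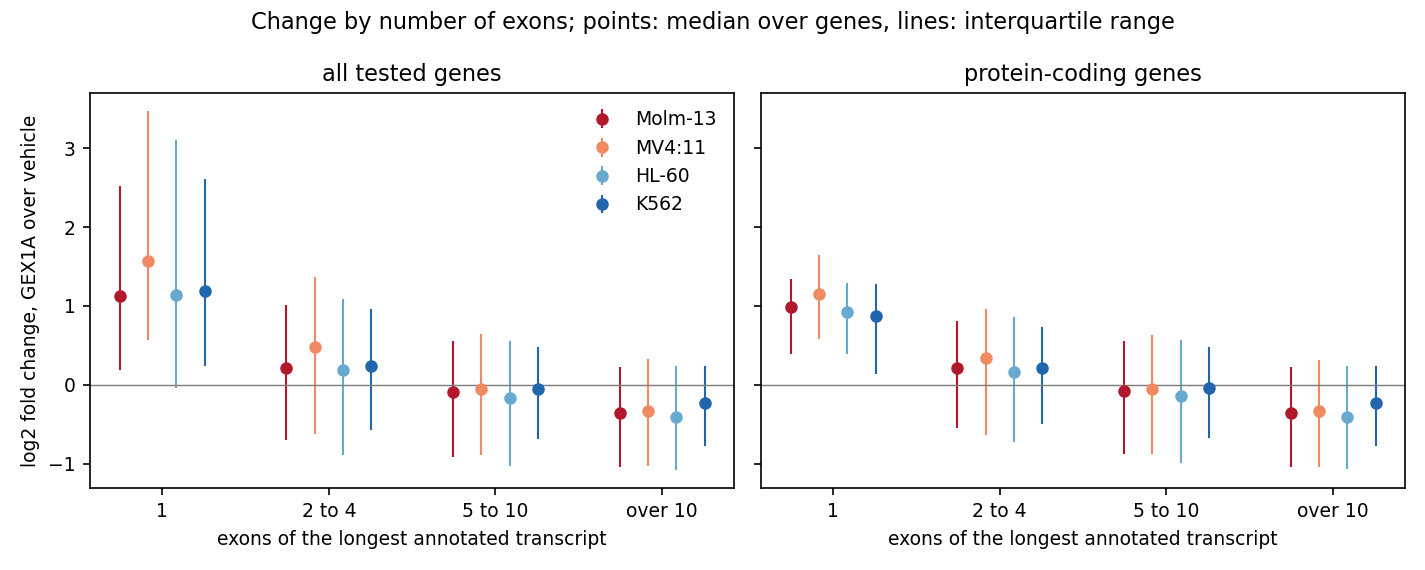
Median log2 fold change with interquartile range (y axis) by number of annotated exons (x axis: 1, 2 to 4, 5 to 10, over 10) in the 4 lines, for all tested genes and for protein-coding genes. The medians fall from between 1.12 and 1.58 for 1 exon to between -0.41 and -0.23 for over 10 exons among all tested genes under TMM scaling, and those of both classes kept their sign by library totals and by upper quartiles. Medians of 2 to 4 exons turned to -0.11 in Molm-13 and -0.28 in HL-60 by library totals, and those of 5 to 10 exons to 0.0061, 0.021 and 0.0035 in Molm-13, MV4:11 and HL-60 by upper quartiles.

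Genes of the splicing machinery rose more often than they fell under TMM scaling, while the medians of the 4 lists turned negative on the TPM scale in HL-60. Unspliced and spliced RNA were not separated, so here and elsewhere a rise need not be of mature mRNA. SF3B1, the core of the SF3b complex that binds the branch point with U2 snRNP, rose from 47.0 ± 1.19 to 67 ± 2.64 in Molm-13, from 47.6 ± 3.30 to 77.7 ± 0.727 in MV4:11, from 96.3 ± 6.87 to 104 ± 6.84 in HL-60 and from 24.2 ± 0.861 to 41.7 ± 1.88 in K562, although the HL-60 log2 change of 0.58 turned to -0.17 on the TPM scale and -0.07 after quantile normalization. PHF5A, which sits beside SF3B1 at the branch point pocket, rose from 46.7 ± 4.23 to 68.2 ± 1.49, from 49.5 ± 6.09 to 86.1 ± 3.98, from 32.0 ± 1.70 to 45.8 ± 1.76 and from 44.4 ± 4.11 to 64.2 ± 7.24. SF3B3 stood at 29.7 ± 0.611 with vehicle and 28.8 ± 1.36 with GEX1A in Molm-13, with log2 changes of 0.28, 0.15, 0.51 and 0.20 that turned negative on the TPM scale in all 4 lines. Of the 22 U2 snRNP and SF3a/SF3b genes tested, 15 rose and 5 fell in Molm-13 and 15 rose and 6 fell in MV4:11. In HL-60, 16 rose and 4 fell, and in K562 17 rose and 4 fell. In Molm-13, 15 rose and 6 fell when adjusted over the list alone. U2 snRNP genes had median log2 changes of 0.71, 0.66, 0.72 and 0.64, turning to -0.03 by TPM in HL-60. Examples are ZRSR2, a recognition factor of minor introns, which fell from 5.17 ± 0.254 to 1.48 ± 0.201 in Molm-13, and SF3B5, which rose from 214 ± 11.5 to 402 ± 11.4. The U2 and SF3 list had adjusted p = 0.00363, 0.0416, 0.00035 and 0.00042 by camera. In all 4 lines these were adjusted p = 0.0441, 0.188, 0.03 and 0.0263 with an estimated correlation. Of the 29 Sm and U1/U4/U5/U6 snRNP protein genes tested, 21 rose and 3 fell in Molm-13 and 20 rose and 6 fell in MV4:11. In HL-60, 21 rose and 7 fell, and in K562 24 rose and 4 fell. In HL-60, 22 rose and 7 fell when adjusted over the list alone. Sm and snRNP genes had median log2 changes of 0.58, 0.42, 0.47 and 0.61, turning to -0.04 by TPM in MV4:11 and -0.01 by library totals and -0.28 by TPM in HL-60. SNRNP40, a U5 component, fell from 22.8 ± 1.64 to 8.04 ± 0.263 in Molm-13. The Sm and snRNP list had adjusted p = 0.000589, 0.0369, 0.00526 and 0.00034 by camera. Camera gave adjusted p = 0.237, 0.398, 0.286 and 0.198 with an estimated correlation in all 4 lines. Of the 19 SR protein and CLK kinase genes tested, 12 rose and 2 fell in Molm-13 and 12 rose and 2 fell in MV4:11. In HL-60, 11 rose and 4 fell, and in K562 13 rose and 4 fell. In HL-60, 12 rose and 4 fell when adjusted over the list alone. SR and CLK genes had median log2 changes of 0.53, 0.55, 0.65 and 0.61, turning to -0.10 by TPM in HL-60. SRSF4 rose from 11.7 ± 0.937 to 31.0 ± 0.338 in Molm-13, and SRPK1, a kinase of SR proteins, fell from 35.2 ± 0.882 to 11.3 ± 0.282. SR and CLK genes had adjusted p = 0.00363, 0.00274, 0.00518 and 0.00407 by camera. Values in all 4 lines were adjusted p = 0.0841, 0.11, 0.129 and 0.126 with an estimated correlation. Of the 23 hnRNP protein genes tested, 15 rose and 5 fell in Molm-13 and 15 rose and 6 fell in MV4:11. In HL-60, 16 rose and 3 fell, and in K562 19 rose and 2 fell. Genes of hnRNP proteins had median log2 changes of 0.42, 0.39, 0.56 and 0.74, turning to -0.08 by TPM in Molm-13, -0.06 by TPM in MV4:11 and -0.18 by TPM in HL-60. HNRNPDL rose from 39.7 ± 0.267 to 83.9 ± 8.65 in K562. The hnRNP list had adjusted p = 0.00366, 0.0359, 0.000544 and 2.47e-07 by camera. For all 4 lines the values were adjusted p = 0.481, 0.494, 0.278 and 0.166 with an estimated correlation.

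Of the 74 cytosolic ribosomal protein genes tested, 72 rose in Molm-13 and 74 rose in MV4:11. In HL-60, 74 rose, and in K562 66 rose. In K562, 67 rose when adjusted over the list alone. Ribosomal protein genes had median log2 changes of 0.60, 0.78, 0.98 and 0.52. These were 0.27, 0.47, 0.51 and 0.29 by library totals and 0.10, 0.32, 0.24 and 0.31 on the TPM scale. RPL30 rose from 123 ± 39.2 to 324 ± 16.0 in Molm-13, and RPL26 rose from 8.19 ± 0.516 to 18.5 ± 0.612 in MV4:11. Ribosomal protein genes had adjusted p = 1.33e-10, 2.6e-13, 2.19e-19 and 7.17e-09 by camera. This became adjusted p = 0.504, 0.355, 0.278 and 0.56 with an estimated correlation in all 4 lines. Of the 27 homologous recombination and Fanconi genes tested, 8 rose and 16 fell in Molm-13 and 7 rose and 15 fell in MV4:11. In HL-60, 5 rose and 19 fell, and in K562 9 rose and 14 fell. Recombination genes had median log2 changes of -0.69, -0.48, -0.91 and -0.25. BRCA1, needed for repair of double-strand breaks, fell from 7.99 ± 0.479 to 1.33 ± 0.128 in Molm-13, from 8.20 ± 0.179 to 1.08 ± 0.138 in MV4:11, from 8.49 ± 0.653 to 1.18 ± 0.105 in HL-60 and from 10.6 ± 0.265 to 3.58 ± 0.860 in K562. FANCL, the ubiquitin ligase of the Fanconi core complex, fell from 8.49 ± 0.696 to 0.791 ± 0.116 in HL-60. Homologous recombination genes had adjusted p = 0.0589, 0.0369, 0.000866 and 0.357 by camera. In MV4:11 and HL-60 these were adjusted p = 0.221 and 0.0824 with an estimated correlation. Of the 13 mitochondrially encoded mRNAs tested, 12 rose in Molm-13 and 12 rose in MV4:11. In HL-60, 13 rose, and in K562 7 fell. In K562, 5 fell when adjusted over the list alone. Mitochondrially encoded mRNAs had median log2 changes of 0.83, 0.70, 1.29 and -0.39. MT-CYB rose from 1377 ± 49.6 to 2547 ± 206 in HL-60. These mRNAs had adjusted p = 0.00363, 0.0229, 0.00028 and 0.357 by camera. Camera gave adjusted p = 0.504, 0.552 and 0.345 with an estimated correlation in Molm-13, MV4:11 and HL-60, and the mitochondrial share of K562 with GEX1A ran from 2.98% to 5.40% between replicates. Of the 15 snoRNA host and NMD-sensitive noncoding genes tested, 10 rose and 3 fell in Molm-13 and 11 rose and 2 fell in MV4:11. In HL-60, 11 rose and 2 fell, and in K562 8 rose and 2 fell. In MV4:11, 12 rose and 2 fell when adjusted over the list alone. Host and noncoding genes had median log2 changes of 0.53, 0.91, 0.92 and 0.66. SNHG17 rose from 11.7 ± 1.32 to 55.7 ± 2.46 in Molm-13. The snoRNA host list had adjusted p = 0.0211, 0.00165, 0.0041 and 0.00496 by camera. Values in all 4 lines were adjusted p = 0.557, 0.355, 0.452 and 0.56 with an estimated correlation.

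In Molm-13, CDKN1A, the inhibitor of cyclin-dependent kinases p21, rose from 44.6 ± 1.77 to 328 ± 13, a log2 change of 3.20 (FPKM ± SD, n = 3, adjusted p = 1.93e-24). GADD45A, a stress gene of growth arrest, rose from 7.04 ± 1.02 to 51.0 ± 2.25, and OVGP1, a secreted glycoprotein gene, from 0.227 ± 0.114 to 6.49 ± 0.373, beside EIF4A1 and DEXI. TNFAIP8L2, a brake on immune signalling, fell from 18.8 ± 0.785 to 1.17 ± 0.306, the Mediator subunit MED29 from 18 ± 0.378 to 1.08 ± 0.0816, the TAK1 partner TAB1 from 14.5 ± 0.0545 to 0.996 ± 0.317, RCSD1 from 21.1 ± 0.598 to 1.88 ± 0.118 and the small GTPase gene RAB7B from 9.31 ± 0.368 to 0.361 ± 0.0963. FLT3, the receptor tyrosine kinase with an internal tandem duplication per the labels, fell from 77.7 ± 3.20 to 19.4 ± 1.72. All 3 treated libraries lay beyond all 3 vehicle libraries for each rise and fall named by rank in this and the other lines. By edgeR, 4822 genes rose and 5874 fell in Molm-13, 66.5% of those tested, against 3351 and 7430 by library totals, 2628 and 8268 on the TPM scale, 5259 and 5394 by upper quartiles, 5289 and 5356 with RLE factors and 5244 and 5357 by DESeq2 (up and down).

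In MV4:11, GADD45A rose from 8.37 ± 0.484 to 106 ± 2.28, the transcription factor gene SCX from 0.864 ± 0.460 to 17 ± 3.24, IFI30, a lysosomal thiol reductase gene, from 0.0889 ± 0.0551 to 7.30 ± 0.503 and DDX39B, an RNA helicase gene of mRNA export, from 6.64 ± 0.315 to 57.0 ± 5.41, beside EIF4A1 (FPKM ± SD, n = 3). HSPA1A, the inducible HSP70 chaperone, fell from 50.8 ± 3.10 to 1.66 ± 0.18, beside FAM117A, RCSD1 from 42.3 ± 0.716 to 3.05 ± 0.245, TMEM104 from 17.2 ± 0.554 to 0.824 ± 0.0953 and STX5, a SNARE gene of the Golgi, from 26.0 ± 0.497 to 1.80 ± 0.405. Of the interferon-stimulated genes, OAS2, the sensor of double-stranded RNA, fell from 21.6 ± 1.01 to 1.49 ± 0.425, IFI6 from 116 ± 10.2 to 12.6 ± 1.37 and OAS1 from 8.70 ± 0.482 to 0.352 ± 0.0966. Of the 24 cholesterol biosynthesis genes, 4 rose and 16 fell (median -0.91, or -0.96 at the bound). Among them, HMGCS1 fell from 16.1 ± 0.497 to 2.55 ± 0.411 and MVD from 11.7 ± 1.18 to 2.78 ± 0.202. By edgeR, 5314 genes rose and 5503 fell in MV4:11, 67.2% of those tested, against 3986 and 6826 by library totals, 3371 and 7391 on the TPM scale, 5598 and 5192 by upper quartiles, 5659 and 5126 with RLE factors and 5621 and 5150 by DESeq2 (up and down). Another gene overlaps 40.2% of the exonic bases of IFI30 and 30.8% of DDX39B on the same strand, and HSPA1A has a near-identical paralog, HSPA1B, so these levels are uncertain.

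In HL-60, FOSB, an AP-1 transcription factor gene, rose from 0.275 ± 0.0220 to 12.1 ± 0.290, RPS10 from 4.11 ± 0.724 to 43.4 ± 2.66 and ZC3H12A, which codes for an mRNA-degrading RNase, from 10.9 ± 0.269 to 95.1 ± 8.65, beside EIF4A1 and DEXI (FPKM ± SD, n = 3). The stress-response transcription factor gene ATF5 fell from 65.3 ± 2.15 to 3.57 ± 0.464, the growth factor gene MDK from 18.6 ± 0.894 to 0.624 ± 0.120, KRCC1 from 13.7 ± 0.693 to 0.318 ± 0.0454, PAQR6 from 11.9 ± 1.70 to 0.225 ± 0.102 and PTER from 11.6 ± 0.851 to 0.327 ± 0.154. CDKN1A fell, the opposite direction from both sensitive lines. Of the 25 immediate early and AP-1 genes, 12 of which also belong to other lists, 15 rose and 3 fell. Their median of 0.47 turned to 0.00 by library totals and -0.28 by TPM. By edgeR, 4903 genes rose and 6022 fell in HL-60, 67.9% of those tested, against 3031 and 8183 by library totals, 2184 and 9351 on the TPM scale, 5619 and 5259 by upper quartiles, 5562 and 5311 with RLE factors and 5460 and 5271 by DESeq2 (up and down).

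In K562, AC010642.1 rose from 0.344 ± 0.115 to 8.65 ± 0.362, RPS17 from 2.0 ± 0.216 to 14.1 ± 1.5 and ZNF324 from 3.64 ± 0.294 to 20.9 ± 0.974, beside DEXI and EIF4A1 (FPKM ± SD, n = 3). PHGDH, the entry enzyme of serine synthesis, fell from 62.8 ± 2.45 to 5.71 ± 0.435 and ASS1, argininosuccinate synthase, from 12.9 ± 1.32 to 0.678 ± 0.148, beside SPRR2D, of a gene family and so uncertain, from 82.6 ± 4.26 to 3.51 ± 1.0, ORAI1 from 16.2 ± 0.764 to 1.2 ± 0.382 and FAM117A from 22.7 ± 0.407 to 2.28 ± 0.546. The erythroid transcription factor gene GATA1 fell from 261 ± 5.01 to 163 ± 11.8. Of the 30 erythroid and megakaryocyte genes, 11 rose and 13 fell (median -0.12, camera adjusted p = 0.357). MCL1, a survival protein gene of the BCL2 family, fell from 130.5 ± 3.97 to 67.7 ± 1.24. By edgeR, 5044 genes rose and 5462 fell in K562, 65.3% of those tested, against 3801 and 6815 by library totals, 3832 and 6670 on the TPM scale, 5316 and 5158 by upper quartiles, 4974 and 5554 with RLE factors and 4870 and 5482 by DESeq2 (up and down). Another gene overlaps 65.4% of the exonic bases of AC010642.1 and 12.7% of RPS17 on the same strand.

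The next comparison asked how the response differed between the sensitive and the resistant lines. Targets of p53 rose in both sensitive lines. CDKN1A rose from 44.6 ± 1.77 to 328 ± 13 in Molm-13 and from 69.9 ± 0.574 to 263 ± 12.8 in MV4:11. It fell from 4.92 ± 0.205 to 0.674 ± 0.284 in HL-60 and from 27.4 ± 2.32 to 5.74 ± 0.109 in K562 (FPKM ± SD, n = 3). MDM2, the ubiquitin ligase that degrades p53, rose from 5.36 ± 0.407 to 21.3 ± 1.54 in Molm-13 and from 9.03 ± 0.147 to 58.7 ± 2.14 in MV4:11, and from 4.36 ± 0.212 to 5.19 ± 0.30 in K562. BBC3, the pro-apoptotic protein PUMA, rose from 6.26 ± 0.472 to 33.2 ± 2.0 and from 8.32 ± 0.552 to 32.9 ± 2.77 in the sensitive lines. It stood at 3.41 ± 0.238 with vehicle and 2.02 ± 0.235 with GEX1A in HL-60 and 9.26 ± 0.852 with vehicle and 7.39 ± 0.745 with GEX1A in K562. GADD45A rose in all 4 lines, from 7.04 ± 1.02 to 51.0 ± 2.25 in Molm-13 and from 139 ± 9.15 to 203 ± 42.1 in K562, with a log2 difference between the classes of 2.80. SESN2, a stress gene that restrains mTORC1, rose from 2.85 ± 0.169 to 8.24 ± 0.933 and from 5.04 ± 0.751 to 15.6 ± 2.24 in the sensitive lines and fell from 19.1 ± 0.321 to 3.39 ± 0.473 and from 12.5 ± 0.253 to 5.26 ± 0.195 in the resistant lines. BTG2, an antiproliferative gene, rose from 4.89 ± 0.380 to 14.2 ± 0.334 and from 15.7 ± 0.437 to 50.8 ± 1.2. It fell from 46.3 ± 1.85 to 14.5 ± 0.455 in K562. Of the 25 p53 targets tested, 19 rose and 3 fell in Molm-13, 18 rose and 4 fell in MV4:11, 9 rose and 13 fell in HL-60 and 6 rose and 10 fell in K562, and adjusted over the list alone 20 rose and 3 fell in Molm-13. Their medians were 1.56, 1.94, -0.29 and -0.06, and the list had adjusted p = 1.23e-07, 7.04e-08, 0.768 and 0.374 by camera. For Molm-13 and MV4:11 the values were adjusted p = 0.00168 and 0.00147 with an estimated correlation. By the contrast of responses 19 were higher and 1 lower in the sensitive lines (21 and 1 adjusted over the list alone), 15 of them in each pair of lines, with a median difference of 1.57 and camera adjusted p = 4.06e-23, and adjusted p = 6.14e-06 with an estimated correlation. TP53 itself fell from 29.8 ± 1.15 to 17.7 ± 1.2 in Molm-13 and from 36.3 ± 2.0 to 14.8 ± 0.687 in MV4:11, and rose from 2.03 ± 0.542 to 3.88 ± 0.854 in K562. It stood at 4.38 ± 0.138 with vehicle and 3.85 ± 0.794 with GEX1A in HL-60.

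**Figure D2:**
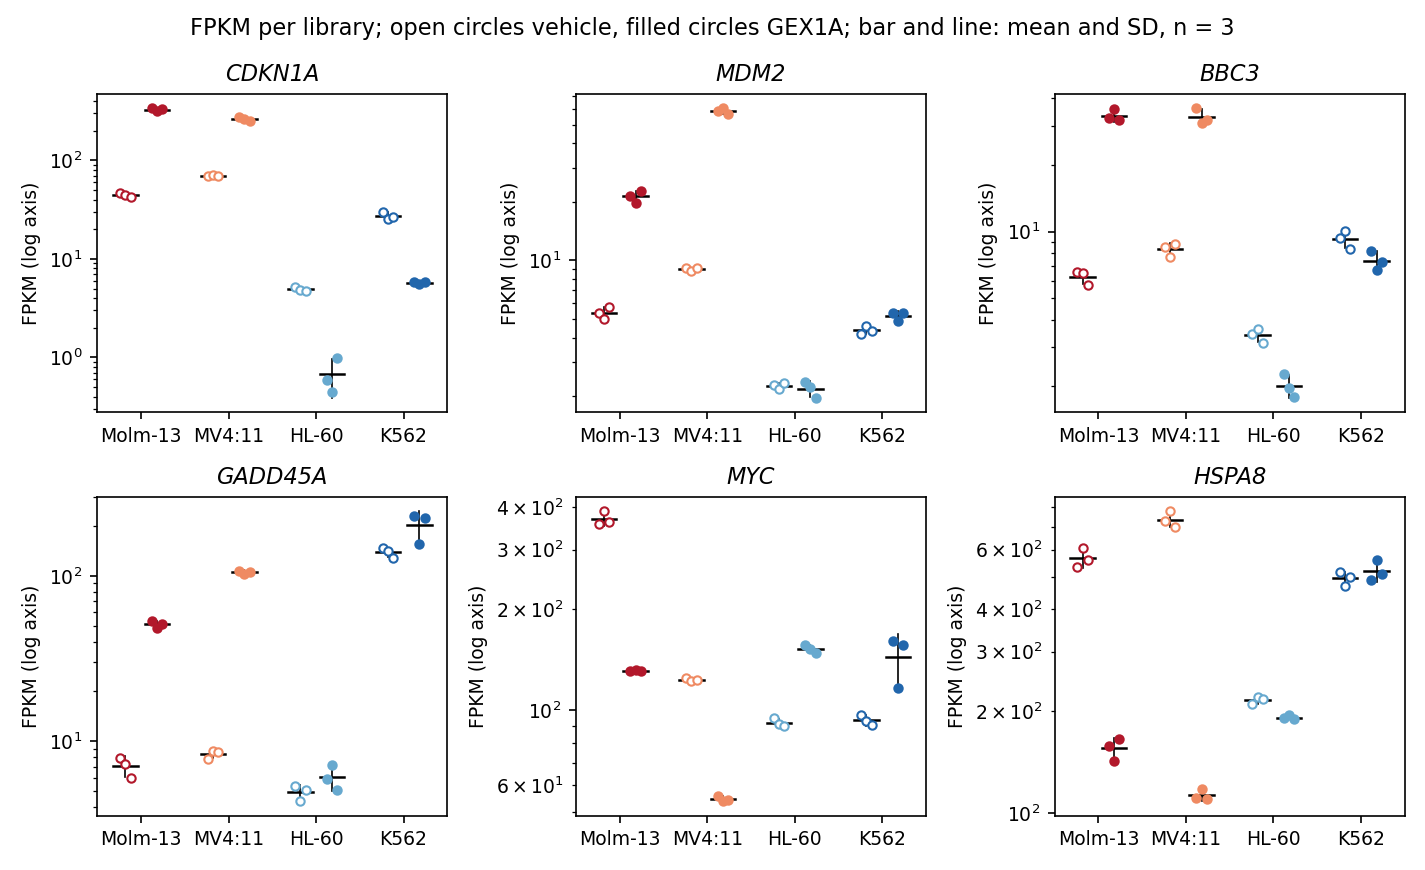
FPKM per library on a log axis of CDKN1A, MDM2, BBC3, GADD45A, MYC and HSPA8 in the 4 lines; open circles are vehicle, filled circles GEX1A, and lines the mean with SD (n = 3). CDKN1A goes from 44.6 to 328 in Molm-13 and from 4.92 to 0.674 in HL-60.

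MYC responded in opposite directions in the classes. MYC fell from 369 ± 17.2 to 131 ± 0.627 in Molm-13 and from 123 ± 1.38 to 54.6 ± 0.885 in MV4:11. It rose from 91.8 ± 2.66 to 152 ± 4.07 in HL-60 and from 93.3 ± 3.36 to 144 ± 24.4 in K562 (FPKM ± SD, n = 3). RRP7A, a ribosome assembly factor gene, fell from 42.6 ± 2.81 to 19.2 ± 2.30 and from 32.6 ± 1.33 to 14.1 ± 1.43 in the sensitive lines and rose from 13.1 ± 0.953 to 22.7 ± 1.01 and from 14.2 ± 1.16 to 17.4 ± 1.33 in the resistant lines. Of the 28 MYC target genes tested, 10 rose and 10 fell in Molm-13 and 12 rose and 11 fell in MV4:11. In HL-60, 22 rose and 5 fell, and in K562 19 rose and 3 fell. In K562, 20 rose and 3 fell when adjusted over the list alone. MYC target genes had median log2 changes of 0.01, 0.02, 0.51 and 0.35, turning to -0.31 by library totals and -0.48 by TPM in Molm-13, -0.30 by library totals and -0.44 by TPM in MV4:11 and -0.24 by TPM in HL-60. The list had adjusted p = 0.881, 0.879, 0.000544 and 0.00143 by camera. This became adjusted p = 0.122 and 0.126 with an estimated correlation in HL-60 and K562. By the contrast of responses 1 were higher and 22 lower in the sensitive lines (1 and 23 adjusted over the list alone), 12 of them in each pair of lines, with a median difference of -0.66 and camera adjusted p = 4.84e-13, and adjusted p = 0.000759 with an estimated correlation. Heat shock genes also differed: HSPA8, the constitutive HSP70 chaperone, fell from 567 ± 36.8 to 155 ± 11.3 in Molm-13 and from 737 ± 38.5 to 113 ± 4.39 in MV4:11. It stood at 216 ± 5.41 with vehicle and 192 ± 2.35 with GEX1A in HL-60 and 494 ± 22.4 with vehicle and 518 ± 37.0 with GEX1A in K562, with fitted log2 changes of 0.30 and 0.30. HSPA1A fell from 2.46 ± 0.198 to 0.796 ± 0.208 in Molm-13, from 50.8 ± 3.10 to 1.66 ± 0.18 in MV4:11 and from 153 ± 11.2 to 81.0 ± 8.85 in K562. Of the 20 heat shock genes tested, 7 rose and 7 fell in Molm-13 and 3 rose and 15 fell in MV4:11. In HL-60, 13 rose and 3 fell, and in K562 12 rose and 4 fell. Heat shock genes had median log2 changes of 0.00, -0.92, 0.39 and 0.45, turning to -0.32 by library totals and -0.49 by TPM in Molm-13 and -0.09 by library totals and -0.36 by TPM in HL-60. Heat shock genes had adjusted p = 0.768, 0.000354, 0.0115 and 0.0106 by camera. In MV4:11, HL-60 and K562 these were adjusted p = 0.203, 0.345 and 0.47 with an estimated correlation. By the contrast 2 were higher and 15 lower in the sensitive lines (2 and 16 adjusted over the list alone), 1 and 8 of them in each pair of lines, with a median of -0.90 and camera adjusted p = 5.61e-13, and adjusted p = 0.0124 with an estimated correlation.

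DDIT4, an mTORC1 inhibitor gene, rose from 1.69 ± 0.365 to 4.45 ± 0.854 in Molm-13 and from 2.96 ± 0.216 to 13.9 ± 0.949 in MV4:11 and fell from 29.1 ± 2.87 to 5.01 ± 0.885 in HL-60 and from 29.2 ± 4.18 to 5.32 ± 0.616 in K562. Another gene overlaps 41.2% of its exonic bases on either strand. GDF15, a stress-induced cytokine gene, rose from 0.125 ± 0.0583 to 2.78 ± 0.861 and from 0.318 ± 0.0549 to 4.41 ± 0.452 in the sensitive lines and fell from 0.756 ± 0.246 to 0.0517 ± 0.0484 and from 230.3 ± 15.8 to 69.0 ± 13.5 in the resistant lines. CYP1B1, a cytochrome P450 gene, rose from 34.4 ± 1.28 to 144 ± 9.74 and from 2.99 ± 0.288 to 19.8 ± 2.62, while its vehicle levels were 0.0256 ± 0.0145 in HL-60 and 0.0340 ± 0.0170 in K562. PICALM, an endocytic adaptor gene, fell from 13.3 ± 0.532 to 3.57 ± 0.152 and from 13.6 ± 0.866 to 2.07 ± 0.167 in the sensitive lines, and TNFSF13B, the B-cell factor BAFF, from 22.9 ± 1.2 to 4.26 ± 0.416 and from 8.96 ± 0.960 to 1.45 ± 0.0991. IFI6 fell from 20.6 ± 2.64 to 11.1 ± 0.331 and from 116 ± 10.2 to 12.6 ± 1.37 there and rose from 72.3 ± 14.1 to 107 ± 17.7 in HL-60. OAS2 had no count in Molm-13 with GEX1A and stood at 0.0846 ± 0.0422 and 0.0307 ± 0.0147 with vehicle in HL-60 and K562, so its class difference rests on MV4:11. Of the 25 integrated stress and unfolded protein response genes tested, 12 rose and 5 fell in Molm-13 and 9 rose and 13 fell in MV4:11. In HL-60, 9 rose and 13 fell, and in K562 2 rose and 17 fell. Stress response genes had median log2 changes of 0.28, -0.43, -0.32 and -0.50, turning to -0.04 by library totals and -0.22 by TPM in Molm-13. The stress list had adjusted p = 0.039, 0.742, 0.779 and 0.00291 by camera. Camera gave adjusted p = 0.504 and 0.465 with an estimated correlation in Molm-13 and K562. By the contrast 13 were higher and 6 lower in the sensitive lines, 7 of them in each pair of lines (median 0.38, camera adjusted p = 0.000287, and adjusted p = 0.296 with an estimated correlation). Of the 27 interferon-stimulated genes tested, 3 rose and 15 fell in Molm-13 and 1 rose and 24 fell in MV4:11. In HL-60, 4 rose and 14 fell, and in K562 2 rose and 6 fell. Interferon-stimulated genes had median log2 changes of -0.53 (-0.55 at the bound), -2.46, -0.68 and -0.32 (-0.39 at the bound). Camera gave adjusted p = 0.353, 3.41e-08, 0.286 and 0.53, and adjusted p = 0.00654 in MV4:11 with an estimated correlation. By the contrast 2 were higher and 13 lower in the sensitive lines, 5 of them in each pair of lines (median -0.97, camera adjusted p = 0.00105, and adjusted p = 0.111 with an estimated correlation).

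**Figure D3:**
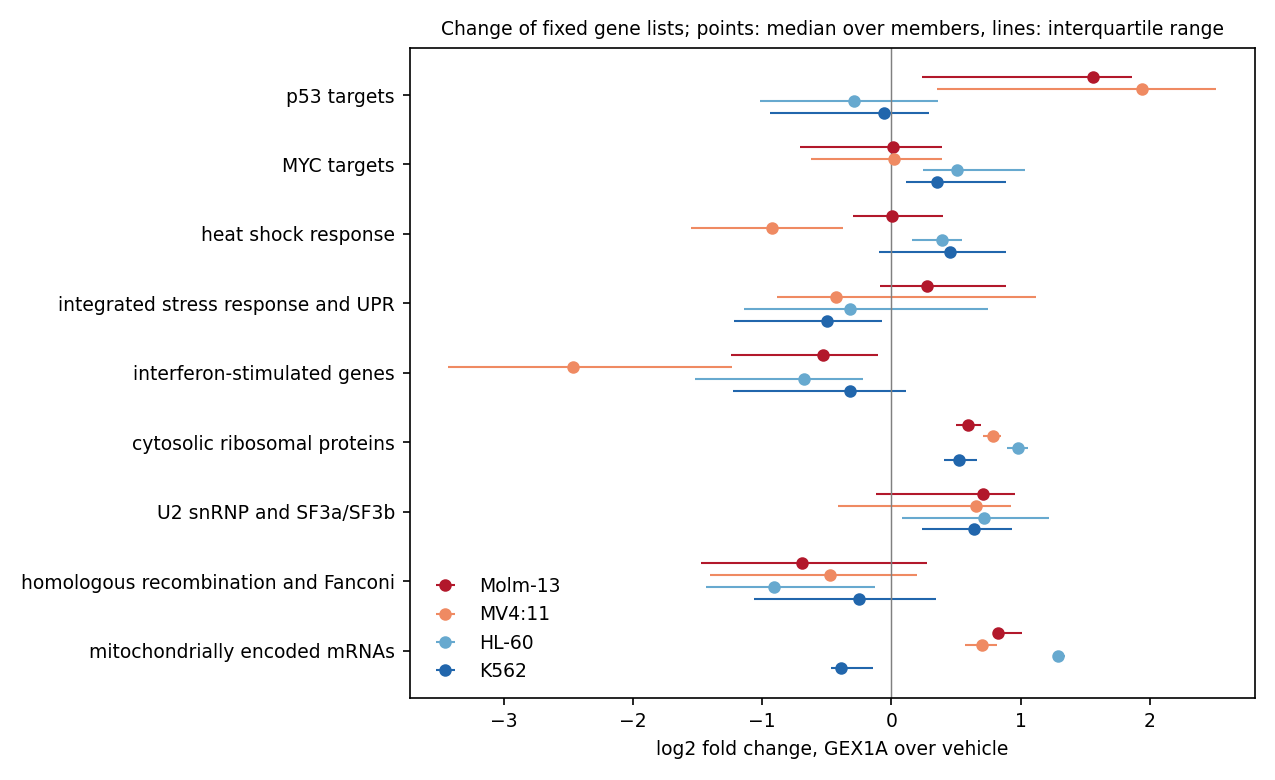
Median log2 fold change with interquartile range (x axis) of 9 fixed gene lists in the 4 lines. Under TMM scaling p53 targets are at 1.56 and 1.94 in Molm-13 and MV4:11 and at -0.29 and -0.06 in HL-60 and K562; medians that change sign on another scaling are those of MYC targets in Molm-13, MV4:11 and HL-60, heat shock genes in Molm-13 and HL-60, stress response genes in Molm-13 and U2 snRNP genes in HL-60.

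In all, the response of 579 genes was higher and of 603 lower in the sensitive lines by the class rule in edgeR. By the contrast alone 5988 passed. Of the genes called in every line, 36 rose in both sensitive and fell in both resistant lines, and 24 did the reverse, where independent lists would give 202 and 192. The counts were 647 and 451 by library totals, 520 and 357 on the TPM scale, 528 and 700 by upper quartiles, 594 and 578 with RLE factors and 616 and 601 by DESeq2. Setting Molm-13 and K562 against MV4:11 and HL-60 gave 1303 genes under the same rule, more than the 1182 of the labelled classes, and each class holds 2 lines.

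The vehicle libraries were compared between the classes to describe how the lines differ before treatment. FLT3 stood at 77.7 ± 3.20, 81.2 ± 3.19, 1.06 ± 0.145 and 0.00423 ± 0.00733 in Molm-13, MV4:11, HL-60 and K562 (FPKM ± SD, n = 3). PRSS57, a serine protease gene of neutrophil granules, was higher in the sensitive lines, at 371 ± 28.9, 152 ± 7.86, 3.92 ± 0.455 and 0.979 ± 0.326, as was ITGAL, the integrin chain CD11a, at 93.4 ± 6.71, 244 ± 8.80, 14.7 ± 0.143 and 0.0461 ± 0.0138, and the chemokine receptor gene CCR2, at 25.3 ± 1.53, 54.7 ± 4.18, 0.0619 ± 0.0242 and 0.0164 ± 0.00276. MYBPH stood at 13.3 ± 0.777, 242 ± 9.54, 1.22 ± 0.113 and 0. CXorf21 stood at 93.6 ± 2.70, 206 ± 9.62, 19.5 ± 1.23 and 0.0430 ± 0.050. The WNT antagonist gene NKD2 stood at 22.5 ± 1.48, 57.5 ± 1.72, 0 and 0.545 ± 0.110. GOLGA8M, of a multicopy family and so uncertain, stood at 36.3 ± 10.9, 28.8 ± 2.96, 0.0229 ± 0.0217 and 0.0773 ± 0.0954. Genes lower in the sensitive lines were MDK at 2.43 ± 0.0493, 0.463 ± 0.214, 18.6 ± 0.894 and 208 ± 11.4, GYPC, which codes for a red cell membrane glycoprotein, at 8.13 ± 0.712, 0.00689 ± 0.0119, 63.8 ± 3.09 and 61.9 ± 4.22. S100P stood at 7.96 ± 0.552, 0.763 ± 0.310, 188 ± 22.4 and 31.4 ± 5.38, TMEM158 at 1.88 ± 0.276, 0.269 ± 0.113, 8.47 ± 0.886 and 121 ± 4.59. The lymphocyte activation gene CD69 stood at 0.711 ± 0.212, 0.00783 ± 0.0136, 13.8 ± 0.621 and 19.4 ± 0.923. GDF15 stood at 0.125 ± 0.0583, 0.318 ± 0.0549, 0.756 ± 0.246 and 230.3 ± 15.8. DLK1 stood at 0.0512 ± 0.0161, 0, 5.16 ± 0.191 and 86.4 ± 0.523 and VCX3A, of another gene family, at 0.108 ± 0.102, 0, 1.31 ± 0.342 and 87.1 ± 2.87. Groups at 0 had no count in 3 libraries.

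Of the 25 MLL fusion target genes, 20 were higher and 3 lower in the sensitive lines by the contrast and 10 higher in each pair of lines, with a median difference of 1.32 and camera adjusted p = 3.94e-07, and adjusted p = 0.0353 with an estimated correlation. PBX3, a HOX cofactor gene, stood at 20.4 ± 0.892, 22.4 ± 0.673, 2.64 ± 0.283 and 0.447 ± 0.0708 in the 4 lines, HOXA9 at 21.6 ± 0.830, 14.6 ± 0.114, 26.9 ± 0.944 and 0 and MEIS1 at 4.02 ± 0.224, 10.3 ± 0.546, 4.21 ± 0.299 and 2.04 ± 0.0527. Of the 21 monocyte and macrophage genes, 16 were higher and 2 lower in the sensitive lines by the contrast and 11 higher in each pair of lines, with a median of 3.04 and camera adjusted p = 3.94e-07, and adjusted p = 0.0878 with an estimated correlation. CSF1R, the receptor of macrophage growth factor, stood at 5.94 ± 0.0498, 9.47 ± 0.219, 0.127 ± 0.0290 and 0.0962 ± 0.0349. Of the 17 neutrophil granule genes, 15 were higher and 1 lower in the sensitive lines by the contrast and 4 higher and 1 lower in each pair of lines (median 2.87, camera adjusted p = 3.94e-07, and adjusted p = 0.0632 with an estimated correlation). AZU1 stood at 1185 ± 144, 476 ± 51.0, 477 ± 12.6 and 1.47 ± 0.345 and MPO at 46.7 ± 1.76, 0.868 ± 0.238, 0.705 ± 0.309 and 0.102 ± 0.0523. Of the 30 erythroid and megakaryocyte genes, 2 were higher and 13 lower in the sensitive lines by the contrast and 1 higher and 4 lower in each pair of lines (median -5.01, or -4.27 at the bound, camera adjusted p = 0.0204, and adjusted p = 0.143 with an estimated correlation), with GATA1 at 0.0111 ± 0.0192, 0.0292 ± 0.0506, 0.0532 ± 0.0463 and 261 ± 5.01 and KLF1 at 0.251 ± 0.113, 0.0838 ± 0.0732, 1.36 ± 0.412 and 95.2 ± 4.49. Of the MYC targets, 25 were higher and 1 lower in the sensitive lines by the contrast and 11 higher and 1 lower in each pair of lines (median 0.58, camera adjusted p = 1.06e-05, and adjusted p = 0.0385 with an estimated correlation), and of the interferon-stimulated genes, 22 were higher and 1 lower in the sensitive lines by the contrast and 1 higher and 1 lower in each pair of lines (median 1.68, camera adjusted p = 0.000607, and adjusted p = 0.0933 with an estimated correlation). Of the p53 targets, 15 were higher and 6 lower in the sensitive lines (15 and 7 adjusted over the list alone) by the contrast and 10 higher and 1 lower in each pair of lines (median 0.86, camera adjusted p = 0.0199, and adjusted p = 0.0933 with an estimated correlation). In all, 1982 genes were higher and 1540 lower in the sensitive lines by the contrast in edgeR and each pair of lines (11078 by the contrast alone), with 1375 and 2076 by library totals, 1473 and 1911 on the TPM scale, 1768 and 1727 by upper quartiles, 1765 and 1708 with RLE factors and 1778 and 1704 by DESeq2. Line origin, medium and class go together in these libraries.

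BCL2L1, the survival gene BCL-XL, rose from 4.02 ± 0.456 to 5.96 ± 0.105 in Molm-13 and from 5.92 ± 0.159 to 10.5 ± 0.711 in MV4:11. It stood at 11.2 ± 0.605 with vehicle and 11.7 ± 0.951 with GEX1A in HL-60 and 58.5 ± 2.53 with vehicle and 55.0 ± 11.2 with GEX1A in K562 (FPKM ± SD, n = 3). Another gene overlaps 43.0% of its exonic bases. BCL2 fell from 13.9 ± 0.390 to 8.76 ± 0.473 in Molm-13, and rose from 21.8 ± 0.720 to 25.9 ± 0.371 in MV4:11. It stood at 2.45 ± 0.0282 with vehicle and 2.29 ± 0.151 with GEX1A in HL-60 and 0.243 ± 0.0422 with vehicle and 0.229 ± 0.0129 with GEX1A in K562. MCL1 rose from 38.1 ± 1.53 to 50.4 ± 2.58 in HL-60 and stood at 45.8 ± 0.952 with vehicle and 44.8 ± 1.06 with GEX1A in Molm-13 and 52.5 ± 1.91 with vehicle and 49.4 ± 0.50 with GEX1A in MV4:11. Of the 10 pro-survival BCL2 family and IAP genes tested, 3 rose and 5 fell in Molm-13 and 4 rose and 4 fell in MV4:11. In HL-60, 4 rose and 4 fell, and in K562 1 rose and 6 fell. Pro-survival genes had median log2 changes of -0.31, 0.04, -0.20 and -0.60, turning to -0.27 by library totals and -0.41 by TPM in MV4:11. These had adjusted p = 0.88, 0.862, 0.876 and 0.158 by camera. Of the 17 pro-apoptotic BCL2 family and caspase genes tested, 5 rose and 10 fell in Molm-13 and 6 rose and 8 fell in MV4:11. In HL-60, 4 rose and 11 fell, and in K562 5 rose and 7 fell. In Molm-13, 6 rose and 10 fell when adjusted over the list alone, and 6 up and 7 down in K562. Pro-apoptotic genes had median log2 changes of -0.50, 0.09 (-0.14 at the bound), -0.57 and -0.12, turning to -0.22 by library totals and -0.36 by TPM in MV4:11. Pro-apoptotic genes had adjusted p = 0.704, 0.879, 0.251 and 0.617 by camera. HOXA9 rose from 21.6 ± 0.830 to 41.9 ± 2.46 in Molm-13, from 14.6 ± 0.114 to 25.1 ± 1.58 in MV4:11 and from 26.9 ± 0.944 to 47.0 ± 1.93 in HL-60, and was listed at 0 in both K562 groups. MEIS1 rose from 4.02 ± 0.224 to 4.37 ± 0.256 in Molm-13 (log2 change 0.44, turning to -0.05 on the TPM scale) and from 10.3 ± 0.546 to 13 ± 0.427 in MV4:11, and fell from 2.04 ± 0.0527 to 1.2 ± 0.0582 in K562. It stood at 4.21 ± 0.299 with vehicle and 2.74 ± 0.481 with GEX1A in HL-60. FLT3 fell from 81.2 ± 3.19 to 41.2 ± 0.263 in MV4:11 and from 1.06 ± 0.145 to 0.372 ± 0.0948 in HL-60. MPO, the granule enzyme myeloperoxidase, stood at 46.7 ± 1.76 with vehicle and 48.4 ± 2.68 with GEX1A in Molm-13. Of the 25 MLL fusion target genes tested, 17 rose and 6 fell in Molm-13 and 13 rose and 7 fell in MV4:11. In HL-60, 14 rose and 7 fell, and in K562 9 rose and 6 fell. In MV4:11, 14 rose and 7 fell when adjusted over the list alone. MLL fusion target genes had median log2 changes of 0.55, 0.32 (0.37 at the bound), 0.47 and 0.24 (0.35 at the bound), turning to -0.13 by TPM in MV4:11 and -0.01 by library totals and -0.29 by TPM in HL-60. The list had adjusted p = 0.00765, 0.0486, 0.0328 and 0.53 by camera. For Molm-13, MV4:11 and HL-60 the values were adjusted p = 0.205, 0.289 and 0.278 with an estimated correlation. In MV4:11 its mean change was -0.10, or 0.05 at the bound.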

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

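Tests chosen after the result was seen are those of the low level of p53 targets, of TP53 status, of reads of a neighbouring gene, of lists without K562 GEX1A replicate 2, of medians at the bound and of whole lines in fits that ignore lines. The results below stand out because the effect of GEX1A differed between the sensitive and the resistant lines by the test of the difference itself.

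Genes with a higher response in the sensitive lines had log2 differences of 4.93 for CDKN1A, 4.28 for DDIT4, 6.88 for GDF15, 3.42 for SESN2, 2.80 for GADD45A, 2.71 for BBC3, 2.56 for BTG2 and 2.95 for CYP1B1. Those with a lower response had -2.27 for HSPA8, -2.28 for IFI6, -2.86 for HSPA1A, -2.05 for MYC, -2.28 for TNFSF13B, -1.76 for RRP7A, -4.57 for OAS2, a fitted value that is no bound since OAS2 had no count in Molm-13 with GEX1A, and -1.95 for PICALM. Median differences of lists called by camera were 1.57 for p53 targets, -0.66 for MYC targets, -0.90 for heat shock genes, 0.38 for stress response genes, -0.97 for interferon-stimulated genes and -0.11 for U2 snRNP genes. They were -0.13 for hnRNP genes, 0.31 (0.30 at the bound) for KRAB zinc finger genes, 0.48 for NF-kB genes and 0.21 (0.20 at the bound) for single-exon genes. Line medians do not part the classes for stress response (0.28, -0.43, -0.32 and -0.50), interferon-stimulated (-0.53, -2.46, -0.68 and -0.32), U2 snRNP (0.71, 0.66, 0.72 and 0.64) and NF-kB genes (-0.02, 0.69, 0.09 and -0.94), nor, unless taken at the bound, for KRAB zinc finger genes (0.23, 0.55, 0.00 and 0.28). Calls lost with the estimate were those of hnRNP, KRAB zinc finger, NF-kB, single-exon, U2 snRNP, stress response and interferon-stimulated genes, at adjusted p = 0.434, 0.269, 0.434, 0.434, 0.111, 0.296 and 0.111 with an estimated correlation.

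Targets of p53 rose in both sensitive lines and not, as a list, in the resistant lines. The tables argue against targets too low to be measured: over the 20 of 25 targets with vehicle FPKM of at least 1 in all 4 lines the median response difference was 1.51, with 19 positive and 12 called in each pair of lines. They also argue against K562 GEX1A replicate 2, which stands apart, since the median was 1.62 without it. In 4 of 4 lines the listed TP53 entry goes with the class, so TP53 status, medium and class cannot be told apart with these lines, and any of them may account for the difference.

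Genes with 1 exon had positive and genes with over 10 exons negative medians in all 4 lines under TMM scaling, with the tested single-exon list at 0.00 on the TPM scale in HL-60. Exonic length is argued against, since protein-coding single-exon genes matched on exonic length and vehicle FPKM still differed from genes with over 10 exons by at least 1.15 in each line. Reads from introns of a host gene are argued against for protein-coding genes, since those lying outside other genes had medians of at least 0.74, but they fit for noncoding genes, where those within a coding gene on the same strand exceeded those outside by at least 1.57, or 1.26 at the bound. Sparing of transcripts that need no splicing stays open, since over protein-coding single-exon genes expressed in the line the smallest median on the TPM scale was 0.18, in HL-60, and no spike-in value was used here to fix the scale.

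Protein-coding genes that rose at least 4-fold in all 4 lines often share exons with another gene. Of 24 such genes, 5 (20.8%) have 50% or more of their exonic bases in another gene, against 27 of 8159 others (0.331%), an odds ratio of 78.7 (95% interval 21.4 to 239, Fisher's exact test, p = 2.66e-08). That excess is the observation itself. It does not decide between how reads shared with a neighbouring or readthrough gene were counted and a biological rise. A low starting level is argued against as the whole cause, with an odds ratio of 23.9 (4.29 to 166) against genes matched on vehicle FPKM.

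Within each line the 6 libraries allow 10 splits, too few for a share under 0.05: 1 split, the real one, gave 10578 genes in Molm-13, 10828 in MV4:11, 10842 in HL-60 and 10204 in K562 by edgeR in fits of each line, and the highest other gave 0, with 89, 62, 58 and 197 genes at unadjusted p under 0.05. For genes changed alike in all 4 lines, 1 of 100 combinations of these splits gave as many as the real 4983, the highest other 0 (0 at unadjusted p under 0.05), which decides nothing, since no other split of any line called a gene to share. Regrouping libraries across classes, 1 of 100 splits gave as many as the real 5781 vehicle differences and 1 of 100 as many as the real 223 response differences in a fit that ignores lines, with a highest other of 0 in both (4467 and 913 at unadjusted p under 0.05 by edgeR). This decides nothing either, since each of the 99 others parts the libraries of a line, and the spread between lines lowers its calls. Other groupings of whole lines in the same fits gave up to 5170 and 166. Regrouping whole lines allows 3 splits, too few for a share under 0.05: 2 of 3 gave at least the 1182 response differences, since Molm-13 and K562 against MV4:11 and HL-60 gave 1303, and for the vehicle comparison 1 of 3 gave 3522, with 2909 the highest other.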

How the results depend on the processing

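Choices made after seeing the data were edgeR, in place of the planned limma with a pseudocount of 1, library totals, RLE factors, DESeq2, the exon classes between 1 and over 10 and, for the lists, leaving out K562 GEX1A replicate 2. Counts of called genes stayed within 1.5 times their main value under every alternative run except 2 kinds. Asking for an absolute log2 change of at least 1 gave 5507 genes in Molm-13, 5880 in MV4:11, 5836 in HL-60, 4721 in K562, 455 for the response difference, 2152 for the vehicle comparison and 1841 shared by all lines, by construction of a stricter rule. Taking 1 pair of lines gave 5051 (Molm-13 against HL-60), 6395 (Molm-13 against K562), 5618 (MV4:11 against HL-60) and 7178 (MV4:11 against K562) response differences, against 5988 by the class contrast alone, and the cause was not tested. Leaving out each library in turn gave 10120 to 10284 genes in Molm-13, 10369 to 10411 in MV4:11, 10466 to 10544 in HL-60, 9860 to 10106 in K562, 1116 to 1200 for the response difference, 3348 to 3448 for the vehicle comparison and 4923 to 5224 shared. DESeq2 gave 10601, 10771, 10731 and 10352 genes in the 4 lines, 10115, 10408, 10082 and 10197 of them with the same sign in edgeR. A replicate block gave 10348, 10585, 10635 and 10109, although same-numbered libraries correlated only between -0.16 and 0.10, so the numbers do not pair them. With limma on log2(FPKM + 1), 282 of the HL-60 genes called by both tools had the opposite sign, and 258 by library totals.

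Of the values of named genes under alternatives, 4932 kept direction and call, 51 were weaker, 45 stronger and 55 reversed. Of the list results 923 kept theirs, 147 were weaker, 78 of these with an estimated correlation, and 18 stronger. The reversed log2 changes were, in the edgeR fit with TMM, BCL2 0.38, BCL2L1 0.53, MDM2 0.43, SF3B1 0.58, SF3B3 0.51, TP53 0.28 in HL-60, GATA1 -0.39 for the response difference, MCL1 0.29, MEIS1 0.44, MPO 0.38, SF3B3 0.28 in Molm-13, MCL1 0.23, SF3B3 0.15 in MV4:11, SF3B1 0.16 for the vehicle comparison and SF3B3 0.20 in K562. Limma with a pseudocount of 1 gave BCL2 -0.0692, MDM2 -0.0337 in HL-60, GATA1 0.35 for the response difference, MCL1 -0.0325, SF3B3 -0.0421 in Molm-13, MCL1 -0.0863, SF3B3 -0.16 in MV4:11, SF3B1 -0.0354 for the vehicle comparison and SF3B3 -0.0302 in K562. Limma with a pseudocount of 0.5 gave BCL2 -0.0815, MDM2 -0.0403 in HL-60, GATA1 0.36 for the response difference, MCL1 -0.0328, SF3B3 -0.0429 in Molm-13, MCL1 -0.0872, SF3B3 -0.16 in MV4:11, SF3B1 -0.0322 for the vehicle comparison and SF3B3 -0.0309 in K562. Limma with a pseudocount of 0.1 gave BCL2 -0.0950, MDM2 -0.0478 in HL-60, MCL1 -0.0331, SF3B3 -0.0435 in Molm-13, MCL1 -0.0878, SF3B3 -0.16 in MV4:11, SF3B1 -0.0296 for the vehicle comparison and SF3B3 -0.0315 in K562. The TPM scale gave BCL2 -0.37, BCL2L1 -0.21, MDM2 -0.32, SF3B1 -0.17, SF3B3 -0.23, TP53 -0.45 in HL-60, MCL1 -0.20, MEIS1 -0.0529, MPO -0.12, SF3B3 -0.21 in Molm-13, MCL1 -0.23, SF3B3 -0.30 in MV4:11 and SF3B3 -0.0119 in K562. Library totals gave BCL2 -0.0953, MDM2 -0.0466 in HL-60, MCL1 -0.0329, SF3B3 -0.0428 in Molm-13, MCL1 -0.0886, SF3B3 -0.16 in MV4:11, SF3B1 -0.0292 for the vehicle comparison and SF3B3 -0.0284 in K562. Limma after quantile normalization gave GATA1 0.63 for the response difference, MCL1 -0.10, MPO -0.0192, SF3B3 -0.0168 in Molm-13, MCL1 -0.0528, SF3B3 -0.0624 in MV4:11, SF3B1 -0.0749 in HL-60 and SF3B1 -0.0543 for the vehicle comparison. The cause was not tested. Medians of genes with 1 exon and with over 10 exons kept their sign under each alternative run for them, at 0.80, 1.27, 0.67 and 0.97 for 1 exon and -0.69, -0.65, -0.89 and -0.46 for over 10 exons by library totals. Those of 2 to 4 exons turned to -0.11 in Molm-13 and -0.28 in HL-60 by library totals and -0.10 in Molm-13, -0.28 in HL-60 and -0.00372 in K562 by limma with a pseudocount of 0.1, and those of 5 to 10 exons to 0.00614 in Molm-13, 0.0213 in MV4:11 and 0.00347 in HL-60 by upper quartiles. In the authors' deposited table the genes that pass per line number 10661, 10933, 11601 and 10619, and 87.2, 90.4, 88.4 and 86.0% of the calls made here that have an adjusted p there pass there with the same sign.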

Other observations

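Fixed lists of cell cycle, signalling and metabolic genes were tested in each line, with medians at the bound added after seeing the results. Of the 29 G2/M and mitosis genes tested, 20 rose and 6 fell in Molm-13 and 8 rose and 17 fell in MV4:11. In HL-60, 11 rose and 13 fell, and in K562 13 rose and 12 fell. G2/M genes had median log2 changes of 0.54, -0.34, -0.10 and 0.11, turning to 0.05 with RLE factors and 0.07 by upper quartiles in HL-60 and -0.12 by library totals and -0.11 by TPM in K562. In Molm-13 BUB1B, a spindle checkpoint kinase gene, fell from 17.9 ± 0.761 to 4.21 ± 0.422 and PLK1 rose from 22.7 ± 1.19 to 51.0 ± 5.42. G2/M genes had adjusted p = 0.000351, 0.0609, 0.876 and 0.533 by camera. This became adjusted p = 0.0841 with an estimated correlation in Molm-13. Of the 27 G1/S and replication genes tested, 11 rose and 12 fell in Molm-13 and 7 rose and 16 fell in MV4:11. In HL-60, 9 rose and 15 fell, and in K562 14 rose and 9 fell. G1/S genes had median log2 changes of -0.10, -0.39, -0.51 and 0.25, turning to 0.00 with RLE factors and by upper quartiles in Molm-13. CDC6, a licensing factor gene of replication origins, fell from 15 ± 0.785 to 2.67 ± 0.107 in MV4:11. G1/S genes had adjusted p = 0.981, 0.0543, 0.05 and 0.483 by camera. Of the 25 immediate early and AP-1 genes tested, 14 rose and 4 fell in Molm-13 and 17 rose and 2 fell in MV4:11. In HL-60, 15 rose and 3 fell, and in K562 7 rose and 11 fell. In Molm-13, 15 rose and 4 fell when adjusted over the list alone. Immediate early genes had median log2 changes of 0.34, 0.73, 0.47 and -0.10 (-0.23 at the bound), turning to -0.15 by TPM in Molm-13 and 0.00 by library totals and -0.28 by TPM in HL-60. Immediate early genes had adjusted p = 0.0132, 0.000639, 0.000333 and 0.715 by camera. In Molm-13, MV4:11 and HL-60 these were adjusted p = 0.504, 0.224 and 0.255 with an estimated correlation. Of the 26 FLT3-STAT5 and MAPK feedback genes tested, 14 rose and 5 fell in Molm-13 and 15 rose and 5 fell in MV4:11. In HL-60, 14 rose and 5 fell, and in K562 8 rose and 7 fell. In MV4:11, 16 rose and 5 fell when adjusted over the list alone, and 7 up and 7 down in K562. Feedback genes had median log2 changes of 0.50, 0.71, 0.44 and -0.01 (-0.06 at the bound), turning to 0.00 by TPM in Molm-13, -0.03 by library totals and -0.30 by TPM in HL-60 and 0.04 by upper quartiles in K562. SPRY2, a feedback inhibitor gene of MAPK signalling, rose from 5.64 ± 0.274 to 16.4 ± 0.916 in Molm-13. Feedback genes had adjusted p = 0.0211, 0.0149, 0.00526 and 0.673 by camera. Camera gave adjusted p = 0.354, 0.224 and 0.255 with an estimated correlation in Molm-13, MV4:11 and HL-60. Of the 20 NF-kB and inflammatory genes tested, 9 rose and 7 fell in Molm-13 and 9 rose and 5 fell in MV4:11. In HL-60, 7 rose and 5 fell, and in K562 3 rose and 11 fell. NF-kB genes had median log2 changes of -0.02 (-0.29 at the bound), 0.69 (0.66 at the bound), 0.09 and -0.94, turning to 0.09 with RLE factors and 0.08 by upper quartiles in Molm-13 and -0.38 by library totals and -0.65 by TPM in HL-60. TNF rose from 13.2 ± 1.29 to 54.5 ± 5.87 in Molm-13. NF-kB genes had adjusted p = 0.573, 0.155, 0.251 and 0.0297 by camera. Values in K562 were adjusted p = 0.47 with an estimated correlation. Of the 21 glycolysis genes tested, 13 rose and 6 fell in Molm-13 and 14 rose and 6 fell in MV4:11. In HL-60, 15 rose and 5 fell, and in K562 12 rose and 7 fell. Glycolysis genes had median log2 changes of 0.42, 0.64, 0.59 and 0.55, turning to -0.08 by TPM in Molm-13 and -0.16 by TPM in HL-60. PFKP, a phosphofructokinase gene, fell from 29.7 ± 0.656 to 6.25 ± 0.946 in Molm-13. Glycolysis genes had adjusted p = 0.0597, 0.0323, 0.00518 and 0.11 by camera. For MV4:11 and HL-60 the values were adjusted p = 0.355 and 0.278 with an estimated correlation. Of the 24 cholesterol biosynthesis genes tested, 11 rose and 10 fell in Molm-13 and 4 rose and 16 fell in MV4:11. In HL-60, 7 rose and 10 fell, and in K562 8 rose and 6 fell. Cholesterol biosynthesis genes had median log2 changes of 0.34 (0.15 at the bound), -0.91 (-0.96 at the bound), -0.06 and 0.01, turning to -0.16 by TPM in Molm-13, 0.03 with RLE factors and 0.04 by upper quartiles in HL-60 and -0.21 by library totals, 0.00 with RLE factors and -0.20 by TPM in K562. Cholesterol genes had adjusted p = 0.157, 0.00191, 0.779 and 0.479 by camera. This became adjusted p = 0.167 with an estimated correlation in MV4:11.

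Other lists covered RNA surveillance, gene classes and cell types. Of the 21 NMD factor genes tested, 8 rose and 9 fell in Molm-13 and 9 rose and 11 fell in MV4:11. In HL-60, 8 rose and 12 fell, and in K562 8 rose and 8 fell. NMD factor genes had median log2 changes of 0.03, -0.40, -0.52 and -0.08, turning to -0.30 by library totals and -0.47 by TPM in Molm-13. CASC3 of the exon junction complex fell from 18.1 ± 0.881 to 4.58 ± 0.0882 in Molm-13. NMD genes had adjusted p = 0.573, 0.879, 0.776 and 0.617 by camera. Of the 22 NRF2 targets tested, 14 rose and 7 fell in Molm-13 and 12 rose and 8 fell in MV4:11. In HL-60, 9 rose and 7 fell, and in K562 12 rose and 7 fell. NRF2 targets had median log2 changes of 0.43, 0.37 (0.34 at the bound), 0.17 (0.14 at the bound) and 0.29, turning to -0.07 by TPM in Molm-13, -0.09 by TPM in MV4:11 and -0.30 by library totals and -0.58 by TPM in HL-60. NRF2 targets had adjusted p = 0.127, 0.636, 0.721 and 0.498 by camera. Of the 63 KRAB zinc finger genes tested, 29 rose and 19 fell in Molm-13 and 35 rose and 13 fell in MV4:11. In HL-60, 25 rose and 18 fell, and in K562 29 rose and 20 fell. In MV4:11, 35 rose and 14 fell when adjusted over the list alone, and 29 up and 22 down in K562. KRAB zinc finger genes had median log2 changes of 0.23 (0.50 at the bound), 0.55, 0.00 (0.22 at the bound) and 0.28, turning to 0.00 by library totals and by TPM in Molm-13 and 0.11 with RLE factors, 0.12 by upper quartiles and -0.27 by TPM in HL-60. ZNF317 rose from 16.8 ± 0.747 to 47.6 ± 2.16 in Molm-13. Zinc finger genes had adjusted p = 0.0132, 0.000846, 0.147 and 0.0106 by camera. In Molm-13, MV4:11 and K562 these were adjusted p = 0.369, 0.188 and 0.465 with an estimated correlation. Of the 41 genes of a hand list of intronless genes tested, 25 rose and 10 fell in Molm-13 and 25 rose and 8 fell in MV4:11. In HL-60, 23 rose and 9 fell, and in K562 15 rose and 14 fell. In Molm-13, 26 rose and 10 fell when adjusted over the list alone, and 24 up and 9 down in HL-60, and 16 up and 15 down in K562. Intronless genes had median log2 changes of 0.65, 0.93, 0.47 and 0.00 (0.01 at the bound), turning to 0.00 by library totals and -0.28 by TPM in HL-60 and -0.21 by library totals and -0.19 by TPM in K562. Hand-listed intronless genes had adjusted p = 0.0126, 0.00191, 0.00503 and 0.416 by camera. Camera gave adjusted p = 0.4, 0.224 and 0.278 with an estimated correlation in Molm-13, MV4:11 and HL-60. Of the 25 replication-dependent histone genes tested, 6 rose and 3 fell in Molm-13 and 6 rose and 6 fell in MV4:11. In HL-60, 7 rose and 1 fell, and in K562 13 rose. In Molm-13, 6 rose and 2 fell when adjusted over the list alone, and 6 up and 5 down in MV4:11, and 6 up and 1 down in HL-60, and 12 up in K562. Histone genes had median log2 changes of -0.02 (0.04 at the bound), 0.12 (0.10 at the bound), 0.74 (0.83 at the bound) and 0.59, turning to 0.05 with RLE factors and 0.04 by upper quartiles in Molm-13 and -0.19 by library totals and -0.34 by TPM in MV4:11. HIST1H1B rose from 0.731 ± 0.449 to 5.39 ± 1.35 in K562. Histone genes had adjusted p = 0.606, 0.862, 0.242 and 0.00576 by camera. Values in K562 were adjusted p = 0.166 with an estimated correlation. Of the 21 monocyte and macrophage genes tested, 2 rose and 10 fell in Molm-13 and 10 rose and 6 fell in MV4:11. In HL-60, 5 rose and 7 fell, and in K562 1 rose and 3 fell. In HL-60, 5 rose and 6 fell when adjusted over the list alone, and 1 down in K562. Monocyte genes had median log2 changes of -0.20, 0.19, -0.25 (-0.18 at the bound) and -0.40, turning to -0.13 by library totals and -0.27 by TPM in MV4:11. Monocyte genes had adjusted p = 0.17, 0.879, 0.768 and 0.617 by camera. Of the 17 neutrophil granule genes tested, 8 rose and 3 fell in Molm-13 and 12 rose and 3 fell in MV4:11. In HL-60, 11 rose and 3 fell, and in K562 3 rose and 8 fell. Neutrophil granule genes had median log2 changes of 0.16, 0.74, 0.77 and -1.23 (-0.55 at the bound), turning to -0.16 by library totals and -0.33 by TPM in Molm-13. GFI1, a granulocyte transcription factor gene, rose from 69.8 ± 2.05 to 221 ± 15.4 in Molm-13. Granule genes had adjusted p = 0.127, 0.0105, 0.00142 and 0.673 by camera. For MV4:11 and HL-60 the values were adjusted p = 0.289 and 0.255 with an estimated correlation. Of the 30 erythroid and megakaryocyte genes tested, 3 rose and 2 fell in Molm-13 and 3 rose and 4 fell in MV4:11. In HL-60, 2 rose and 1 fell, and in K562 11 rose and 13 fell. In Molm-13, 2 rose and 2 fell when adjusted over the list alone, and 3 up and 2 down in MV4:11, and 1 up in HL-60. Erythroid genes had median log2 changes of 0.00 (-0.10 at the bound), 0.00 (-0.16 at the bound), 0.00 and -0.12, turning to -0.05 by library totals and -0.22 by TPM in Molm-13 and -0.15 by library totals and -0.28 by TPM in MV4:11. Erythroid genes had adjusted p = 0.77, 0.937, 0.768 and 0.357 by camera. Lymphocyte markers (6 tested) and stromal and epithelial markers (7 tested), listed as signs of other cell types, had medians of -0.60, -0.14, -0.34 (-0.67 at the bound) and 0.14 (0.16 at the bound), turning to -0.08 by library totals and -0.07 by TPM in K562, and of 0.07, 0.01, -0.48 (-0.29 at the bound) and 0.49, turning to -0.24 by library totals and -0.41 by TPM in Molm-13 and -0.30 by library totals and -0.45 by TPM in MV4:11. Lymphocyte markers had adjusted p = 0.683, 0.931, 0.876 and 0.751 by camera, and stromal markers adjusted p = 0.695, 0.862, 0.876 and 0.617 by camera.

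In the vehicle libraries, further lists were higher in the sensitive lines, with median differences by the contrast of 0.56 for heat shock, 0.58 for hnRNP, 0.33 for Sm and snRNP, 0.26 for U2 snRNP, 0.40 for ribosomal protein and 0.35 for G1/S genes. In each pair of lines 7, 10, 7, 7, 20 and 9 were higher, and 1 G1/S gene lower. Their camera adjusted p = 0.0186, 7.36e-05, 0.0318, 0.0115, 0.000111 and 0.0204, and adjusted p = 0.45, 0.256, 0.499, 0.0704, 0.841 and 0.525 with an estimated correlation. The median, the mean and the camera direction of a list differed in sign for erythroid, G1/S, glycolysis, heat shock response, MYC targets, NF-kB, NRF2, histones and stromal in Molm-13, MLL fusion targets, MYC targets, NMD, pro-apoptotic, stromal and lymphocyte in MV4:11, erythroid, monocyte, NRF2 and lymphocyte in HL-60, FLT3-STAT5, G2/M, immediate early, MLL fusion targets and NRF2 in K562. In MV4:11 those of NRF2 genes and histones differed only with the mean at the bound, -0.07 and -0.04.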
